A study of Homo sapiens with 6 samples.

How the data were processed

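Messenger RNA levels were measured on 6 Illumina human HT-12 BeadChip arrays, a platform on which biotin-labelled cRNA binds to bead-bound probes and each probe gives one brightness value. The arrays covered stable derivatives of H1299, an established human non-small cell lung carcinoma line that the labels describe as lung adenocarcinoma. There were 2 clones stably transfected with Lin-28B and 1 control line for them, and 2 clones stably transfected with Ago2 and 1 control line for them. Groups and clone numbers were taken from the sample titles. RNA came from cells growing exponentially, was extracted with Trizol and was amplified and labelled with an Ambion MessageAmp kit, per the labels' protocols and the series' design text.

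The authors deposited 1 table of linear probe intensities, with 48803 probes on each array. The scanner software, the background handling and the normalization behind these deposited intensities are not given in the sources used here, and neither are detection calls. Tested on the values, the array medians lay between 61.7 and 67.04 and the lowest value of an array between 26.1 and 43.4. A background level was therefore still present in the deposited intensities, which compresses the fold changes of dim probes. The sorted values differed between arrays, so the table had not been quantile normalized to 1 distribution. Arrays have no read depth, and their number limits the precision.

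The table pairs its probe identifiers with no gene names, and none of the 48803 probes was named here (0 names). A RefSeq gene table of assembly GRCh38.p14 was at hand, but it holds no probe identifiers and was not used. The planned check of LIN28B and AGO2, the 32 gene lists written before the data were examined (among them let-7 targets, the microRNA pathway, cell cycle genes and markers of other cell types), the let-7 seed sites and the averaging of the probes of a gene were therefore not analysed here. Chromosomal positions of the probes were not analysed here either.

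Intensities were set to at least 1, 32 was added, log2 was taken and the arrays were quantile normalized. A fold change is thus on the log2(intensity + 32) scale and understates changes of dim probes. Probes above their array's median on at least 2 of the 6 arrays were kept, which left 28035 probes (57.4%). All 6 arrays entered 1 linear model with 4 groups in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation. The model had 2 residual degrees of freedom, which come only from the spread between the 2 clones of each transfection. A control with 1 array was assumed to vary like the clones. The moderation added 2.54 prior degrees of freedom around a prior SD of 0.105. P-values were adjusted by the Benjamini-Hochberg method over the kept probes, with a threshold of 0.05. Contrasts were each transfection against its own control, the difference between these 2 effects, and 1 control against the other. A direct comparison of the Lin28B clones with the Ago2 clones was added after the data had been examined. Because the design has so few arrays, a rule of size without a test was also fixed beforehand: at least 2-fold from the control, in the same direction, in both clones. A permutation test of 2 clones against 1 control has 3 arrangements and a smallest possible p of 0.333 in an exact test, so none was used. The labels do not say that clones were cultured or hybridized on separate days, so p-values measure only the spread between these arrays.

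The rule for naming features was fixed before the data were examined and required a gene symbol. Without symbols it was applied to probes, and the number printed per comparison was limited to 2 in each direction. For Lin28B and for the difference of effects these are the largest changes past the threshold. For Ago2, where none passed, they are the probes whose smaller change of the 2 clones was largest.

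The fit was tested on simulated data with the fitted spread: 5 draws of 28035 probes, with 200 probes changed in the clones of 1 transfection. For the Lin28B comparison, 15.6% of probes changed by 1 on the log2 scale were called, 84.8% of those changed by 2, 95.6% of those changed by 3 and 96.0% of those changed by 4. For the Ago2 comparison the shares were 10.8%, 81.2%, 91.6% and 97.2%. These shares apply to 200 changed probes per draw, to controls that vary like the clones and to a spread drawn without regard to signal. The observed spread was wider for bright probes. Between the Ago2 clones the SD was 0.295 over kept probes and 0.389 above the 70th percentile of mean signal. The shares may thus not hold for bright probes. In the data, the 4 named Ago2 probes, with log2 changes of 3.25, 3.52, -4.43 and -3.32, were not called. An absence of Ago2 calls thus does not exclude large changes. Over all 5 draws, the Lin28B comparison made 54 false and 730 true calls (6.89% false, above the adjusted threshold of 0.05). The Ago2 comparison made 34 false and 702 true calls (4.62% false). Both comparisons had the same simulated design and spread, so the gaps between them come from the small number of draws. Unchanged clones sharing 1 control were simulated in 20 draws to give the chance level of agreement between clones, with each probe's spread drawn from the fitted prior. A first version, which used each probe's residual SD and gave a mean of 78.7 probes at least 2-fold changed, was replaced by this one after its result had been seen. Arrays drawn from the prior varied more on average than the observed clones did, so the chance values are approximate. The same spread was used for 6 unchanged arrays, simulated after the data had been examined, to give the chance shares of probes with a control beyond all other arrays or with all clones between the controls. Alternatives covered the normalization, the offset, the filter, the control group, the arrays in the fit, the variance moderation, the size rule, leaving out each clone, and the clone number as a block. The labels tie no Lin28B clone to an Ago2 clone. Figures were drawn with matplotlib 3.10.9.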

Results

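The series compared H1299 lung carcinoma cells stably transfected with Lin-28B or with Ago2 against control lines. LIN28B is an RNA-binding protein that blocks maturation of the let-7 microRNAs, and AGO2 is the Argonaute protein that carries microRNAs in the silencing complex. The question, as the series title gives it, was how the mRNA profile differs after each transfection. The data were 6 arrays: 2 Lin28B clones with 1 control, and 2 Ago2 clones with 1 control. Median intensities were 64.8 and 67.04 on the Lin28B and Ago2 control arrays, 64.2 and 62.5 on the arrays of Lin28B clones 1 and 2, and 61.7 and 63.4 on those of Ago2 clones 1 and 2. Of 48803 probes, 28035 were kept. Fold and log2 changes are on the normalized log2(intensity + 32) scale, and intensities are as deposited. Results are given per probe, because the probes carry no gene names here. The levels of LIN28B and AGO2 themselves, which could check the labels of the clones, were not analysed here. Such a check works only where the transfected sequence holds the sequence of the probe.

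The 4 transfected clones resembled one another more than any of them resembled either control, and the 2 controls were the farthest apart of all 15 pairs. The SD over probes of the log2 difference between arrays was 0.214 between the 2 Lin28B clones and 0.295 between the 2 Ago2 clones. Between a Lin28B clone and an Ago2 clone it ranged from 0.243 to 0.287, which lies within the range of the 2 within-transfection values. A clone and its own control differed by 0.371 to 0.438, a clone and the other transfection's control by 0.314 to 0.415, and the 2 controls by 0.548. At least 2-fold differences were seen for 65 probes between the Lin28B clones, 336 between the Ago2 clones and 2303 between the controls. Pearson's r across probes, which are not independent replicates, was 0.991 for the Lin28B clones, 0.983 for the Ago2 clones and 0.942 for the controls.

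**Figure D1:**
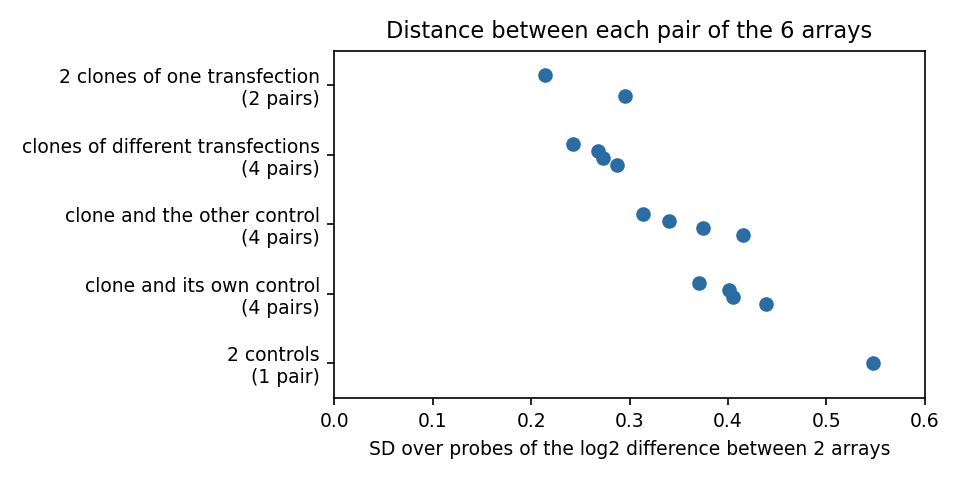
Each point is 1 of the 15 pairs of arrays, and the x axis is the SD over 28035 probes of the log2 difference between both arrays. The pair of controls lies at 0.548, beyond the 8 pairs of a clone with a control, and all 6 pairs of clones lie at 0.295 or below.

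The first comparison asked which transcripts differed between the Lin28B clones and their control. In limma with Benjamini-Hochberg adjustment, 463 probes passed an adjusted p of 0.05, of which 231 were higher and 232 lower in the clones. The median size of their change was 1.20 on the log2 scale. ILMN_1767658 rose 6.75-fold, from an intensity of 279 in the control to 2179 ± 405 (SD, n = 2) in the clones, with a log2 change of 2.75 ± 0.27 (SE). ILMN_2383305 rose 6.56-fold, from 251 to 1954 ± 759 (SD, n = 2), a log2 change of 2.71 ± 0.32 (SE). ILMN_1663640 fell from 939 to 64.2 ± 3.5 (SD, n = 2), near the array medians, a log2 change of -3.45 ± 0.10 (SE) with the smallest adjusted p of the comparison, 0.0322. With both clones near background this size depends on the offset: it was -2.78 with an offset of 100 and -3.99 with no offset. ILMN_1678671 fell from 828 to 144 ± 13 (SD, n = 2), a log2 change of -2.40 ± 0.12 (SE). The other named probes had an adjusted p of 0.0488. Against the Ago2 control in place of their own, the 4 changes were 0.22, -0.69, 0.031 and 0.12 in this order, none past the threshold in limma.

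By the size rule, 716 probes (2.55% of those kept) differed at least 2-fold from the control in the same direction in both Lin28B clones, 340 higher and 376 lower. Unchanged clones sharing 1 control gave a mean of 111 such probes and at most 140 in 20 simulated draws. The observed count was 255 against the Ago2 control, 53 with pooled controls and 457 with an offset of 100. The simulated control varied like the clones, so the excess may come from the control array. The changes of both clones correlated across probes at 0.875, against 0.526 for simulated unchanged clones, and their covariance was 0.155 against 0.0599. The simulated covariance comes from the shared control, whose simulated spread was wider than that of the observed clones of either transfection. It is thus an approximate level. The control array was the one that stood apart, which the selection forces in part, since a called probe differs between the control and its own clones. For 457 of the 463 called probes (98.7%) the Lin28B control lay beyond all 5 other arrays, the Ago2 clones and the Ago2 control included. Over all kept probes this share was 52.4%, against 33.3% of all probes among simulated unchanged arrays. Of the 463, 406 (87.7%) were also called between the 2 controls, against 5.97% of all kept probes, but both comparisons use the same Lin28B control array and part of this overlap may come from it. Of the 716 probes at least 2-fold changed, the control lay beyond all 5 others for 97.5%, against 75.6% of such probes among simulated unchanged arrays. Calls clustered at the threshold: only 1 of the 463 had an adjusted p under 0.045. Normalization by cyclic loess left 1 call, and exchanged controls left 0. The count was 1 with robust moderation and 0 with an offset of 100 (smallest adjusted p 0.0633), with the controls pooled, or without Lin28B clone 1 or clone 2 (smallest adjusted p 0.252 and 0.206). It was 2357 without either Ago2 clone. Pooling counts the gap between the controls as spread, which favours 0 calls. Leaving out a clone leaves 1 residual degree of freedom from 1 pair of clones, so those counts depend on which pair is left. The split between higher and lower depended on the scaling. With arrays only shifted to a common median, 70.4% of 470 calls were higher, and without quantile normalization 61.97% of 476. In the quantile-normalized data the share was 49.9%.

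The second comparison asked the same of the Ago2 clones and their control. No probe passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.0999. At an unadjusted threshold of 0.05, 4239 probes passed, where 1402 would by chance. At an adjusted threshold of 0.10 there were 12, 6 higher and 6 lower. With an intensity trend in the moderation limma called 161, with the stricter filter 2, and with robust moderation 0. Without Ago2 clone 2 the count was 51, and without Ago2 clone 1 it was 0.

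By size, 347 probes (1.24%) differed at least 2-fold from the Ago2 control in both Ago2 clones, 179 higher and 168 lower, against a mean of 111 for simulated unchanged clones. The observed count was 388 against the Lin28B control, 36 with pooled controls and 218 with an offset of 100. The simulated control varied like the clones, so the excess does not tell a transfection effect from a control array that stands apart. With arrays only shifted to a common median, 65.2% of 388 such probes were higher, against 51.6% here. For Lin28B the same scaling gave 66.9% of 724 and no quantile normalization 62.1% of 705, against 47.5%. The probes with the largest changes shared by both Ago2 clones are given as values, since none passed the test. ILMN_1792455 measured 1597 in the Ago2 control and 15144 ± 302 (SD, n = 2) in the clones, a 9.50-fold difference and a log2 change of 3.25 ± 0.18 (SE, adjusted p = 0.0999). It measured 10030 in the Lin28B control and 3951 ± 577 (SD, n = 2) in the Lin28B clones. ILMN_1660436 measured 321 in the Ago2 control and 4236 ± 1416 (SD, n = 2) in the clones, a log2 change of 3.52 ± 0.31 (SE, adjusted p = 0.102). ILMN_1660067 measured 3122 in the control and 121 ± 86 (SD, n = 2) in the clones, a log2 change of -4.43 ± 0.55 (SE, adjusted p = 0.106), which was -3.87 with an offset of 100 and -4.83 with no offset. ILMN_1658448 measured 1032 in the control and 72.1 ± 16.8 (SD, n = 2) in the clones, a log2 change of -3.32 ± 0.21 (SE, adjusted p = 0.0999), which was -2.69 with an offset of 100 and -3.81 with no offset. Both clones of ILMN_1658448 and clone 1 of ILMN_1660067 lay near the array medians. Against the Lin28B control in place of their own, the changes of the 4 probes were 0.48, 0.91, -0.069 and 0.24 in this order. For 336 of the 347 probes (96.8%) the Ago2 control lay beyond all 5 other arrays, a share that was 44.7% over all kept probes (33.3% among simulated unchanged arrays) and 75.6% of such probes among simulated unchanged arrays. The changes of both Ago2 clones correlated at 0.709 across probes, against 0.526 for simulated unchanged clones, with a covariance of 0.105 against 0.0599.

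**Figure D2:**
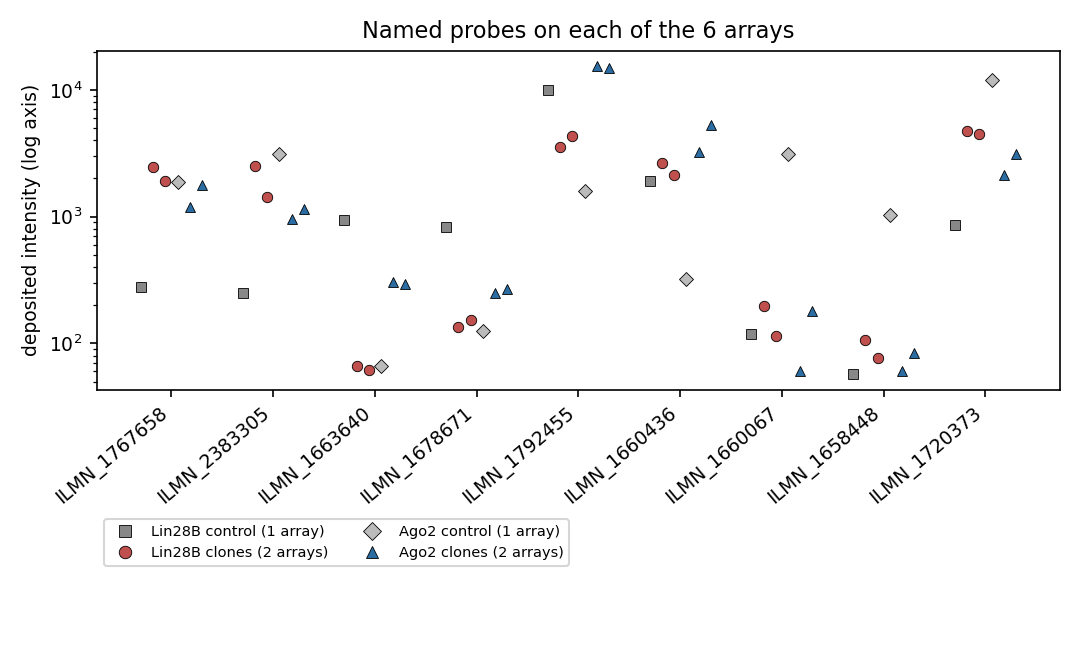
Deposited intensity (log axis) of the 9 named probes on each of the 6 arrays, with squares and diamonds for the single control arrays and circles and triangles for the clones. For ILMN_1663640 the Lin28B control (939) lies above the other 5 arrays, and for ILMN_1658448 the Ago2 control (1032) does.

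The third comparison tested the difference between both effects, each taken against its own control. It passed for 1067 probes in limma, 559 with a higher and 508 with a lower Lin28B effect. This difference equals the direct difference between Lin28B clones and Ago2 clones, which gave 0 calls, minus the difference between the 2 single control arrays, which gave 1674. Both parts entered the named values. For ILMN_1720373, ILMN_2383305, ILMN_1663640 and ILMN_1792455 the clones differed directly by 0.81, 0.79, -1.75 and -1.98 on the log2 scale, none past the threshold in limma, and the controls by -3.60, -3.41, 3.49 and 2.77. With exchanged controls the test gave 0 calls. ILMN_1663640 differed by -5.23 ± 0.14 on the log2 scale (SE, adjusted p = 0.0236), a size that depends on the offset because 2 of its 4 groups lay near the array medians: it was -4.05 with an offset of 100 and -6.22 with no offset. This probe was lower in the Lin28B clones than in their control and measured 65.9 in the Ago2 control and 299.6 ± 8.2 (SD, n = 2) in the Ago2 clones. ILMN_1792455 differed by -4.75 ± 0.25 (SE, adjusted p = 0.0405). ILMN_1720373 differed by 4.41 ± 0.32 (SE, adjusted p = 0.0405), with 853 in the Lin28B control, 4612 ± 219 (SD, n = 2) in the Lin28B clones, 11999 in the Ago2 control and 2618 ± 697 (SD, n = 2) in the Ago2 clones. ILMN_2383305 differed by 4.20 ± 0.46 (SE, adjusted p = 0.0409). Leaving out Lin28B clone 1 or clone 2 left 0 calls, with a smallest adjusted p of 0.175 and 0.149. Leaving out Ago2 clone 1 gave 2499 calls and leaving out Ago2 clone 2 gave 2887. With an offset of 100 there were 0, with a smallest adjusted p of 0.0532.

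Each taken against its own single control array, both effects had opposite signs for 58.7% of all kept probes. The 2 effects share no array, and their correlation across probes was -0.371 (Pearson) and -0.293 (Spearman). Controls that lie on opposite sides of the clones give a negative correlation by themselves. Opposite action of the 2 transfections is therefore not shown. The correlation was negative for each of the 4 pairs of 1 Lin28B and 1 Ago2 clone, from -0.407 to -0.287. All 4 pairs use the same 2 control arrays, so they are not independent. Of the probes at least 2-fold changed in both clones of both transfections, 62 went in opposite directions, where independent lists would share 4.44, and 4 went in the same direction, where 4.42 would be shared. Compared directly, without the controls, Lin28B clones and Ago2 clones gave 0 calls in limma, with 1952 probes at an unadjusted threshold of 0.05, where 1402 would pass by chance. Robust moderation also gave 0 and the intensity trend gave 2.

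**Figure D3:**
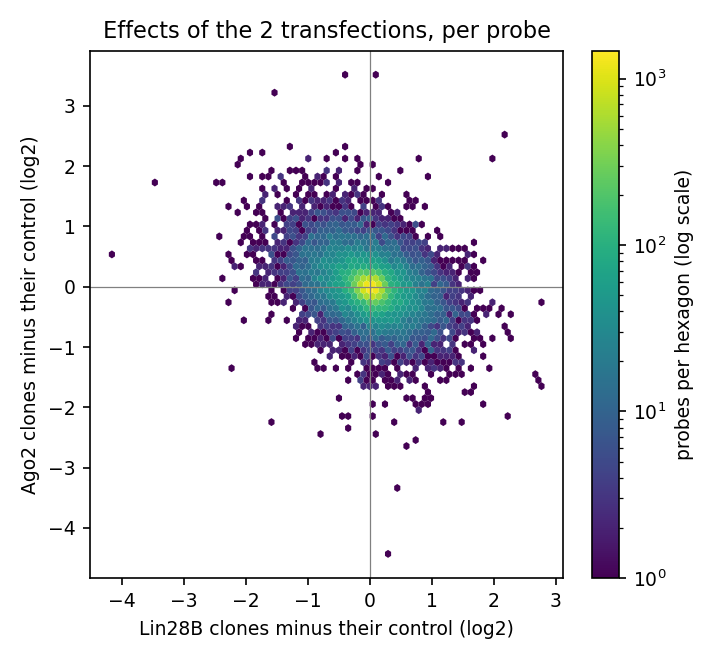
Log2 change of each of the 28035 probes in the Lin28B clones (x axis) and in the Ago2 clones (y axis), each against its own control, with color for the number of probes per hexagon on a log scale. The cloud slopes downward, with a Pearson correlation across probes of -0.371.

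The controls were compared with each other on 1 array each, with the spread taken from the clones and no replicate check of their own. Between them 1674 probes passed an adjusted p of 0.05 in limma, 842 higher in the Lin28B control and 832 higher in the Ago2 control. The count was 0 without either Lin28B clone and 4000 without either Ago2 clone. Of the 2303 probes at least 2-fold apart between the controls, 1265 were higher in the Lin28B control and 1038 in the Ago2 control. All 4 clones lay between both controls for 1507 of these (65.4%), which the selection forces in part: the share was 27.7% for such probes among simulated unchanged arrays. Over all kept probes it was 19.5%, against 6.60% among unchanged arrays. On a scale from 0 at the Ago2 control to 1 at the Lin28B control, the median position was 0.362 for the Lin28B clones and 0.480 for the Ago2 clones. The first principal component held 50.4% of the variance, with the Lin28B control at one end (51.5), the Ago2 control at the other (-39.2) and the 4 clones between -13.3 and 8.56.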

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

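The correlation between both effects and the test of their difference were planned, whereas the use of that correlation against an explanation, the other explanation tests, the direct comparison of clones and the exchange of controls were chosen after the result had been seen. The difference between both effects, each against 1 control array, passed the test for 1067 probes, and among these it was 4.41 for ILMN_1720373, 4.20 for ILMN_2383305, -5.23 for ILMN_1663640 and -4.75 for ILMN_1792455 on the log2 scale. Without the controls, the clones differed in the same direction by 0.81, 0.79, -1.75 and -1.98, none past the threshold in limma, where the direct comparison gave 0 calls and 1952 probes at an unadjusted threshold of 0.05. Picking the largest differences of effects favours probes whose clone and control parts add up, so the shared direction is no separate support. For ILMN_1663640 both the clone difference and the gap between the controls depend on the offset, because the Lin28B clones and the Ago2 control lay near the array medians. The rest of each value is the gap between 2 single control arrays, so the size is not shown to be a difference between the transfections. With the controls exchanged the values were -2.79, -2.62, 1.74 and 0.79. These follow from the same clone and control parts with the sign of the control gap turned, so they are no further check.

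The 2 control arrays lay farther apart than any clone lay from its control. An intensity-dependent bias between arrays would have been removed by cyclic loess, after which the SD between the controls was still 0.537, against 0.298 for the more distant pair of clones. Noise of dim probes is argued against by an SD of 0.737 among probes above the 70th percentile of mean signal, against 0.389 for that pair of clones. A single poor control array as the whole cause is argued against by the correlation of -0.371 between both effects, which share no array. Each control also lay farther from all 4 clones (0.314 or more) than any 2 clones from each other (0.295 at most), a narrow margin. The Lin28B control array did stand apart in its deposited intensities. Its minimum was the lowest (26.1, against 34.8 to 43.4 on the other arrays) and its maximum the highest (45656, against 30362 to 37194). A partial contribution of that array's quality therefore stays open. Whether a state that varies between all the lines, such as growth state, clonal drift or RNA quality, sets the controls apart cannot be told. Across probes, the difference between the controls correlated at -0.193 with that between the Lin28B clones and at 0.170 with that between the Ago2 clones. These correlations share at most 3.72% of the variance. The 2 clone differences correlated with each other at -0.204, the sign that 1 common state would give. Clones of a pair lie close together, so a small share does not weigh against such a state. The rule for this explanation was first a correlation over 0.1 in size, which these values meet, and a share of at least 50% of the variance was required only after they had been seen. Separate origins of the control lines and a processing batch stay open, because each control is 1 array and the probes are unnamed.

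On average, each control lay nearer to the other transfection's clones than to its own. The clones' mean SD was 0.361 from the other control and 0.404 from their own. Opposite effects of both transfections on 1 common starting state would require similar controls, and the SD of 0.548 between them, against 0.295 for the more distant pair of clones, argues against that as the whole cause. Exchanged control labels may also give this order and cannot be told apart from lines of different origin, with 1 array per control. Neither control is labelled as carrying either gene. The LIN28B and AGO2 probes, not analysed here, could therefore check the clones but not which control is which. With exchanged controls the correlation of the effects was still negative (-0.197).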

How the results depend on the processing

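The SDs between arrays moved by less than 1.5 times under every scaling, offset and filter tried, and the effect correlation stayed between -0.389 and -0.308 without each clone in turn; only exchanged controls moved it further, to -0.197. The counts of calls depended strongly on the settings, and the cause was not tested except where stated. Cyclic loess, normexp, no offset, exchanged controls, the crossed block and the direct comparison of clones were added after the data had been examined. For Lin28B against its control (463) the count was 0 with an offset of 100, pooled controls or exchanged controls, 1 with robust moderation or cyclic loess, 721 with an intensity trend, 736 with normexp, 738 with the 70th percentile filter, 813 with no offset and 2357 with only its own 3 arrays; without each replicate it ranged from 0 to 2357. For Ago2 (0) it was 2 with the 70th percentile filter and 161 with an intensity trend, and 0 to 51 without each replicate. The difference of effects (1067) gave 0 with an offset of 100 or exchanged controls, and 0 to 2887 without each replicate. The control comparison (1674) gave 1003 with an offset of 100, and 0 to 4000 without each replicate, which leaves 1 residual degree of freedom from 1 pair of clones: the closer Lin28B pair gives more calls and the wider Ago2 pair fewer. The direct comparison of clones (0) gave 2 with an intensity trend. The number of Lin28B probes at least 2-fold changed (716) was 457 with an offset of 100, 53 with pooled controls, 255 with exchanged controls and 2779 at 1.5-fold, and 1031 to 1301 with 1 clone; for Ago2 (347) it was 218, 36, 388 and 1594, and 713 to 919. Same-numbered clones deviated apart (correlation -0.204) and share only a number; the replicate block on the difference of effects gave 0 calls and the crossed replicate block 1743. With exchanged controls the Lin28B changes shrank to -0.69 for ILMN_2383305, 0.031 for ILMN_1663640 and 0.12 for ILMN_1678671. The Ago2 change of ILMN_1658448 shrank to 0.24. These values had the opposite sign but were small beside the changes against their own control. The differences of effects became -2.79, -2.62, 1.74 and 0.79, which follows from turning the sign of the gap between the controls. Quantile normalization shifted no array's median over kept probes by more than 0.022 in size. The alternative that averages the probes of a gene, and all alternatives for the gene lists and let-7 targets, were not run because the probes are unnamed. A control could not be left out, having 1 array. Signal near background limits what dim probes can show.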
